A study of Rattus norvegicus with 120 samples.

How the data were processed

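Kidney RNA of male Sprague-Dawley rats was measured on 120 Affymetrix Rat 230 2.0 arrays, 1 per rat. Each rat was given olive oil (vehicle), cyclosporine (CsA), tacrolimus (FK506) or rapamycin (Rapa) by intraperitoneal injection once a day, and the kidneys were taken 24 hours after the last of 1, 7, 14 or 28 doses. Per the labels, total RNA was turned into biotin-labelled cRNA in a one-cycle protocol, and each array was scanned after hybridization. The deposited values are intensities on a linear scale, from 0 to 30646; the labels do not state how the authors summarized the probes or scaled the arrays. In the intensity table the mean of each array after trimming 2% at both ends ran from 232.89 to 250.1, a ratio of 1.07. The medians on the log2 scale ran from 6.09 to 6.67. All 5273 zeros of the table were in 1 array, where they made up 17.0% of the values. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.986.

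An offset of 16 was added to each intensity, the log2 was taken, and the arrays were quantile normalized because their medians differed while their trimmed means did not. Of 31099 probe sets, 57 were controls, 20826 carried the symbol of 1 gene, 436 carried several and 9780 carried none. For each of 14217 genes the probe set with the highest mean was kept. The 25% of genes with the lowest mean over all arrays were left out as dim (3554 genes), which left 10663 genes. A linear model with 1 mean per group was fitted to all 120 arrays with limma 3.58.1 in R 4.3.3, so that all groups shared 1 estimate of the spread with 92 residual degrees of freedom and 2.95 prior degrees of freedom. Tests were two-sided, moderated by empirical Bayes without an intensity trend. P values were adjusted over the genes of each comparison by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Errors of log2 changes are the standard errors (SE) of this model, and errors of group levels are standard deviations (SD). Arrays carry no counts, so the number of rats limits the precision.

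There were 28 groups: 7 treatments at 4 days. Each treated group was compared with the vehicle rats of its day (24 comparisons). The higher doses of FK506 and Rapa were also compared directly at each day, and the lower doses at day 28. The other comparisons were CsA 25 mg/kg with FK506 6 mg/kg, the higher with the lower dose of each drug, the change of each higher-dose effect from day 1 to day 28, and vehicle at day 28 with vehicle at day 1. This made 37 comparisons. A set of calcineurin inhibitor genes was defined as those called in the same direction for CsA 25 mg/kg and for FK506 6 mg/kg at day 28, both against vehicle and against Rapa 10 mg/kg. Different rats were killed at each day, and the replicate numbers did not pair rats, so no blocking was used. The labels gave no batch or scan date.

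The processing, the comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. In the higher-dose comparisons with vehicle at day 28 the rule named the 10 largest rises and the 10 largest falls. It took them among called genes for which each treated rat lay on the same side of the vehicle mean. In each other comparison it named up to 4 rises and 4 falls, in each described list up to 4 members with the largest absolute change, and in the set of calcineurin inhibitor genes 10 rises and 10 falls. In addition 22 kidney genes were named in advance, of which 19 were measured. Of 38 fixed lists of kidney cell types, pathways and other tissues, 36 had at least 5 measured members and were tested. The test was limma's camera with a preset correlation between genes of 0.01, adjusted over 864 tests (36 lists in 24 comparisons), with camera using an estimated correlation and fry beside it. Members were counted as called over all genes and adjusted over the list alone. The similarity of 2 drugs was measured as the correlation and covariance of log2 changes across genes and as the number of shared calls. These were set against simulated groups with no effect that shared simulated vehicle rats. They were also set against a split in which each drug was compared with a different part of the real vehicle rats. Detection by the model and the list test was tested on simulated data.

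Those alternatives were the table without quantile normalization, an offset of 1, no filter on dim genes, all probe sets kept apart, an intensity trend in the empirical Bayes step, a fit to the arrays of the compared days alone, a limit of 0.01 for the calcineurin inhibitor genes, and leaving out each rat in turn in groups of up to 5 rats. Further alternatives were chosen after seeing the data. They were the log2 ratio of the 3-prime to the 5-prime Gapdh probe set as a covariate (a measure of RNA quality and labelling), the mean level of the hybridization controls as a covariate, leaving out replicate 4 of Rapa 1 mg/kg at day 28, leaving out 4 arrays with a log2 level of Alb above 12, leaving out the array with zeros in the list tests and the similarity at day 28, and the list tests without quantile normalization or with the Gapdh covariate. Genes without a symbol or with several symbols were left out of the counts. The blood chemistry and histopathology that the labels mention were not among the deposited files.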

Results

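Gene expression was measured in kidneys of 120 male Sprague-Dawley rats aged 5 to 7 weeks, with 1 array per rat. The series was set up, by its title, to look for genomic markers by which kidney toxicity of calcineurin inhibitors could be found early. Cyclosporine (CsA) and tacrolimus (FK506) inhibit calcineurin, the phosphatase that activates the NFAT transcription factors of T cells. Rapamycin (Rapa), a macrolide like FK506 that binds the same intracellular protein, inhibits the kinase mTOR instead. Rats received CsA at 2.5 or 25 mg/kg, FK506 at 0.6 or 6 mg/kg, Rapa at 1 or 10 mg/kg, or olive oil, for 1, 7, 14 or 28 days. Each group held 4 rats, except 3 for FK506 6 mg/kg at day 14. At day 28 there were 5 rats for vehicle, CsA 2.5 mg/kg and FK506 6 mg/kg, 4 for CsA 25 mg/kg and 6 for FK506 0.6 mg/kg and each Rapa dose. The median intensity per array ran from 51.99 to 86.08, and the second lowest was 63.69. The lowest belonged to CsA 25 mg/kg at day 28, replicate 3, the array that held all zeros of the table. Its mean correlation with the other arrays of its group was 0.870, against at least 0.940 for every other array. Levels below are log2(intensity + 16), and changes are differences of log2 levels. Each gene named as among the largest rises or falls against vehicle lay on the same side of the vehicle mean in every treated rat. In other comparisons of 2 groups the mean of the second group was used instead. For the changes of an effect from day 1 to day 28 no such check was made.

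**Figure D1:**
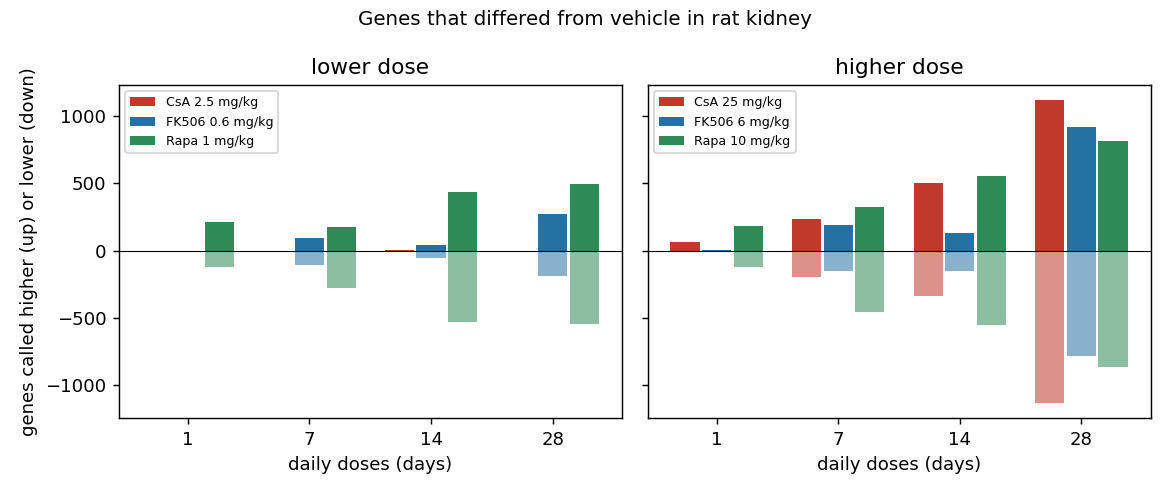
Numbers of genes called higher (above 0) and lower (below 0) than in vehicle rats of the same day, for each drug and dose, by day. The count at CsA 25 mg/kg went from 66 higher and 6 lower at day 1 to 1120 and 1135 at day 28, and CsA 2.5 mg/kg gave 0 calls at days 1, 7 and 28.

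CsA 25 mg/kg after 28 doses was compared with vehicle to find transcripts that mark prolonged exposure. Genes of the injured tubule were higher and genes of the distal convoluted tubule lower. Havcr1 (1387965_at), the kidney injury molecule shed by damaged proximal tubule cells, rose by 4.42 (SE 0.52, adjusted p = 2.34e-10), from 6.03 ± 0.58 (SD, n = 5) in vehicle to 10.46 ± 1.08 (SD, n = 4). Calb1 (1370201_at), a calcium-binding protein of the distal tubule, fell by 3.39 (SE 0.23, adjusted p = 6.37e-22), from 12.15 ± 0.37 to 8.76 ± 0.28. Slc12a3 (1387230_at), the thiazide-sensitive sodium chloride cotransporter, fell by 1.76 (SE 0.18, adjusted p = 2.63e-12), and Egf, the epidermal growth factor made in the distal nephron, fell by 1.27. Further rises were Cxcl13, a chemokine that attracts B cells (3.01, adjusted p = 0.000159), Cldn4 of tight junctions (2.39), the metalloprotease Adamts1 (2.32), the myeloid receptor Pilra (2.29), the secreted chaperone Clu (1367784_a_at, 2.29, adjusted p = 1.56e-09), the stress transcription factor Atf3 (2.26), Spp1 or osteopontin (1367581_a_at, 2.21, adjusted p = 5.67e-08) and the siderophore-binding Lcn2 (1387011_at, 2.21, adjusted p = 0.000428). Timp1, an inhibitor of metalloproteinases, rose by 1.68, Tgfb1 by 0.80, Vim by 0.75 and Cyp27b1, which activates vitamin D, by 1.05, while Umod of the thick ascending limb fell by 0.25. The male-specific cytochrome Cyp2c11 (1387328_at) fell by 4.78 (SE 0.81, adjusted p = 3.78e-06). The other 8 of the 10 largest falls rested in size on the array with zeros. Without CsA 25 mg/kg replicate 3 the urate transporter Slc22a12 went from -2.65 to -1.01, Dhrs7l1 from -2.60 to -0.55, Eri2 from -2.46 to -1.31 (no longer called), the transcription factor Hnf4a from -2.31 to -0.28, Afmid from -2.30 to -1.03, Hykk from -2.29 to -0.55, Gba3 from -2.26 to -0.48 and Susd2 from -2.20 to -0.76. In the same fit Calb1 was -3.35, Cyp2c11 -4.88, Slc12a3 -1.76 and Havcr1 4.20. The rise of Serpina3n, a protease inhibitor (2.26), lost its call without that array (1.62), without vehicle replicates 2, 4 or 5 or without CsA replicate 4, at values from 1.62 to 2.35. Cyp27b1 lost its call without CsA replicate 4 (0.81), and Vim moved to 0.49. In all, 1120 genes were higher and 1135 lower, 304 of the called genes by more than 2-fold, and 1685 were called without the array with zeros.

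Among the fixed lists at CsA 25 mg/kg and day 28, tubular injury genes were higher and distal convoluted tubule genes lower. Of 27 tubular injury genes, 16 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 0.92 (adjusted p = 1.54e-11; adjusted p = 0.0096 with an estimated correlation). Of 18 distal convoluted tubule genes, 8 fell and 1 rose, the same numbers adjusted over the list alone (adjusted p = 4.64e-07; adjusted p = 6.15e-05 with an estimated correlation). They included Slc8a1, the sodium-calcium exchanger of that segment (-1.35), and Emx1 (-1.29). Of 25 genes of the unfolded protein response, 13 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 0.00857 with an estimated correlation), among them Asns (1.42), Manf (0.80) and Dnajb9 (0.75). Ribosomal protein and translation genes moved by small amounts in 1 direction. Of 48, 40 rose and 1 fell (42 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 0.00768 with an estimated correlation), as in Rps15a (0.50) and Rpl6 (0.46), while Rpl26l1 fell by 0.81. Of 18 genes of vitamin D and calcium-phosphate handling, 4 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0383 with an estimated correlation). Calb1, S100g, Slc8a1 and Trpv5 are in both this and the distal convoluted tubule list, so the 2 calls are not separate. Of 22 macrophage and myeloid genes 18 rose (19 adjusted over the list alone), among them Fcer1g (1.40) and Ptprc (1.14), but this list lost its call with an estimated correlation (adjusted p = 0.105). Without the array with zeros the first 5 of these lists kept their calls with an estimated correlation, at adjusted p values from 0.000143 to 0.0193.

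After 14 doses of CsA 25 mg/kg injury genes were higher and distal tubule genes lower, and after 7 doses distal tubule genes were lower and myeloid genes higher. At day 14 Havcr1 was higher by 4.14 (SE 0.55, adjusted p = 3.62e-08), Lcn2 by 2.61, Spp1 by 1.75, Clu by 1.70 and Timp1 by 1.21, while Calb1 fell by 2.60 (SE 0.25, adjusted p = 8.65e-14), Slc12a3 by 1.27 and Egf by 0.71. At day 7 Calb1 fell by 2.33 (SE 0.25, adjusted p = 1.17e-11) and Slc12a3 fell by 1.96 (SE 0.19, adjusted p = 9.13e-13), while Havcr1 differed by 0.71 (adjusted p = 0.566). The B-cell chemokine Cxcl13 rose by 3.74 at day 7 and 3.38 at day 14, the Fc receptor Fcgr3a by 2.25 and 2.64, and Pilra by 2.57 and Spn, a leukocyte surface protein, by 1.55 at day 7. Macrophage and myeloid genes rose as a list at day 7 (10 of 22, or 16 adjusted over the list alone; adjusted p = 0.0425 with an estimated correlation) and day 14 (13, or 15 over the list alone; adjusted p = 0.0255 with an estimated correlation). Examples at day 7 were Fcer1g (1.47), Adgre1 (1.28) and the complement subunit C1qa (1.16). At day 14 tubular injury genes (15 of 27 higher, 17 over the list alone; adjusted p = 0.00522 with an estimated correlation), the unfolded protein response (8 of 25 higher, 15 over the list alone; 0.00159 as adjusted p with an estimated correlation), immediate early genes such as Fos (1.90) and Egr1 (1.80) (11 of 22, 14 over the list alone; 0.0173) and ribosomal protein genes (35 of 48, 36 over the list alone; 0.0107) also rose. The distal convoluted tubule list was lower at both days, with 6 and 7 called members (7 each adjusted over the list alone; adjusted p = 3.33e-05 and 0.000523 with an estimated correlation). At day 14 Cyp2c11 (-3.12), the fibrinogen chain Fgb (2.80), Rasd2 (-1.42), Urah (-1.43) and Umod (-0.23) lost their calls when a single rat was left out. These were CsA replicate 2 for Cyp2c11 (-2.78), 3 for Fgb (2.50), 4 for Rasd2 (-1.08), any of 5 rats for Urah (-1.20 to -1.49) and any of 3 for Umod (-0.19 to -0.21). At day 7 the fall of Egf (-0.47) was not called without CsA replicate 1 (-0.40), and the haemoglobin gene Hbb (-1.56) and the mitochondrial carrier Slc25a25 (-1.55) also fell. Day 14 gave 504 higher and 337 lower genes and day 7 gave 234 and 194, or 239 in all without CsA 25 mg/kg replicate 4 of day 7. The log2 ratio of 3-prime to 5-prime Gapdh, a measure of RNA quality, differed between the groups of day 7, at 0.727 in vehicle and 0.426 with CsA 25 mg/kg. With this ratio as a covariate 356 genes were called at day 7, and Calb1 was at -2.10 and Slc12a3 at -1.59. The distal convoluted tubule and myeloid lists were then called, but by the preset correlation alone, which calls many lists in randomly dealt rats.

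A single dose of CsA 25 mg/kg gave 66 higher and 6 lower genes. The largest rises were the urea cycle enzyme Arg1 (3.18), Apob of lipoproteins (3.13), Cyp2d3 (2.66) and Fetub (2.62), all transcribed at a high level in liver. In the same group Alb, the gene of serum albumin, was at 14.38 and 14.49 in replicates 3 and 4, against 4.60 to 6.61 in the other 6 rats of this comparison. Without the 4 arrays of the series with Alb above 12, Arg1 was 0.52, Apob 0.19, Cyp2d3 0.47 and Fetub 0.16, none of them called, and 5 genes were called in all. The largest falls, Ptgs2 or cyclooxygenase-2 (-1.48), Rem1 (-0.83), Amhr2 (-0.83) and Cib2 (-0.64), also lost their calls there, at -1.62, -0.91, -0.78 and -0.63, and in a fit to day 1 alone. The count was 6 without replicate 3 alone, and Apob, Fetub, Cyp2d3, Ptgs2, Rem1, Amhr2 and Cib2 were not called then (2.15, 1.77, 1.87, -1.48, -0.81, -0.66 and -0.67). Apob (2.14), Fetub (1.83), Ptgs2 (-1.57) and Cib2 (-0.60) were not called without replicate 4 either. Calb1 differed from vehicle by -0.74 (adjusted p = 0.223) and Slc12a3 by -0.18. The distal convoluted tubule list as a whole lay lower, with 0 of 18 members called, or 2 adjusted over the list alone (median -0.17, adjusted p = 0.00933 with an estimated correlation). Interferon response genes were higher (2 of 22 called, 9 over the list alone; adjusted p = 0.0324 with an estimated correlation), led by the antiviral Mx2 (1.77) and Mx1 (1.38). Fatty acid synthesis genes were also higher (0 of 13 called, 3 over the list alone; adjusted p = 0.0158 with an estimated correlation), but not without the arrays with high Alb (adjusted p = 0.294).

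The lower CsA dose, 2.5 mg/kg, tested how far these changes depend on dose. Limma called 0 genes at days 1, 7 and 28 (248, 850 and 425 at an unadjusted p under 0.05) and 7 at day 14, where Rnf41 rose by 1.54 and lost its call without vehicle replicate 2 (1.11). Of its 2 other probe sets (0.05 and 0.58) none was called. The other 6 day 14 calls included Begain (1.13), Safb (0.79), Ppp1r26 (0.73), Dchs1 (-0.79) and Mustn1 (-0.63), each of which lost its call without any of at least 3 single rats (0.59 to 1.12 and -0.52 to -0.72). In replicate 4 of this group Alb, made at a high level in liver, was at 13.50. Without the 4 arrays of the series with Alb above 12, Begain (1.10), Safb (0.67) and Dchs1 (-0.67) were not called, and 4 genes were called in all. None of the 36 lists was called with an estimated correlation at this dose. The direct comparison of 25 with 2.5 mg/kg at day 28 gave 940 higher and 1022 lower genes, and 1355 in all without the array with zeros. Havcr1 was higher at the higher dose by 4.75 (SE 0.52, adjusted p = 1.6e-11), Lcn2 by 2.39, Spp1 by 2.35 and Adamts1 by 2.34. Calb1 differed by -2.96 (SE 0.23, adjusted p = 3.78e-18), with a level of 11.71 ± 0.49 (SD, n = 5) at 2.5 mg/kg. Cyp2c11 differed by -2.88, and without the array with zeros Slc22a12 went from -2.60 to -0.96 and Dhrs7l1 from -2.51 to -0.45.

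FK506 6 mg/kg after 28 doses was the other calcineurin inhibitor set against vehicle. It too had higher injury genes and lower distal tubule genes. Havcr1 rose by 3.64 (SE 0.49, adjusted p = 3.36e-08), to 9.68 ± 1.44 (SD, n = 5), Clu by 2.01, Spp1 by 1.89, Lcn2 by 1.83, Cldn4 by 1.67 and Timp1 by 1.40. Calb1 fell by 3.04 (SE 0.22, adjusted p = 1.55e-20), to 9.11 ± 0.34, Slc12a3 fell by 1.72 (SE 0.17, adjusted p = 8.47e-13) and Egf fell by 1.37. Serpina3n (2.78), the kallikrein Klk1c9 (2.14), the fibrinogen chains Fga (1.78) and Fgb (1.85), the lysosomal glycoprotein Gpnmb (1.70) and Cyp27b1 (1.44) also rose. Falls outside the distal tubule were Cyp2c11 (-4.33, SE 0.76, adjusted p = 1.29e-05), the sterol hydroxylase Cyp8b1 (-1.97), the glucagon receptor Gcgr (-1.92), Gc, the vitamin D binding protein (-1.79), Slc51a, a subunit of the organic solute transporter (-1.75), Tm4sf20 (-1.72) and Gtpbp4 (-1.61). Of 27 tubular injury genes 16 rose and 1 fell (16 and 2 over the list alone; adjusted p = 0.0107 with an estimated correlation). Of 18 distal convoluted tubule genes 7 fell and 1 rose (8 and 1 adjusted over the list alone; adjusted p = 2.55e-05 with an estimated correlation). Vitamin D and calcium-phosphate genes were lower (6 of 18, 8 over the list alone; adjusted p = 0.0107 with an estimated correlation), with the receptor Vdr at -0.61, and 37 of 48 ribosomal protein genes rose (38 over the list alone; 0.0107). Macrophage and myeloid genes (11 of 22 higher, 13 over the list alone) lost their call with an estimated correlation (adjusted p = 0.329). The arrays of this group had a mean hybridization control level of 9.43 ± 1.00 (SD, n = 5), against 10.6 to 11.2 in the groups other than this and Rapa 1 mg/kg at day 28. With that level as a covariate Gc (-1.44), Lcn2 (1.32), Serpina3n (1.35), Fgb (1.53), Poteml2 (-1.78, then -1.70), Tgfb1 (0.68, then 0.45) and Vim (0.71, then 0.51) lost their calls, and Gpnmb moved to 1.08. Fgb lost its call without any of 8 single rats (1.59 to 1.95), Poteml2 without any of 5 (-1.49 to -1.81) and Tgfb1 without vehicle replicate 1 (0.45). In all 920 genes were higher and 784 lower, 96 of them by more than 2-fold, and 727 were called with that covariate.

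The distal tubule genes were also lower after 7 and 14 doses of FK506 6 mg/kg, and Havcr1 was higher at both. At day 7 Slc12a3 fell by 2.14 (SE 0.19, adjusted p = 1.09e-14), Calb1 changed by -2.08 and Egf by -0.89, and Havcr1 rose by 2.58 (SE 0.55, adjusted p = 0.00225). At day 14 Calb1 was at -2.67 (adjusted p = 1.35e-12), Slc12a3 at -1.34, Egf at -0.87, Umod at -0.41 and Havcr1 at 3.71 (SE 0.59, adjusted p = 2.66e-05), with Spp1 at 1.55 and Clu at 1.5. The enzyme Glyatl2 rose (1.37) and Ptgs2 (-1.66) and Hbb (-1.61) fell at day 7, and at day 14 Rasd1 rose (2.09) and Mvd, of sterol synthesis, fell (-1.56). The distal convoluted tubule list was lower at each day, with 6 of 18 members called at day 7 (7 adjusted over the list alone) and 8 at day 14 (9 over the list alone), at adjusted p = 6.78e-06 and 1.45e-06 with an estimated correlation. Vitamin D and calcium-phosphate genes were lower at day 14 (5 of 18, 7 over the list alone; adjusted p = 0.00236 with an estimated correlation). Tubular injury genes at day 14 lost their call with an estimated correlation (adjusted p = 0.113). At day 14 Alb was at 11.11 in FK506 replicate 2, and 9 of the 120 arrays lay above 10. At this day Fgb (3.08; 2.68 without FK506 replicate 2), Fga (1.88; 1.51 without it, 1.79 without vehicle replicate 1) and Kl, the phosphate-regulating klotho (-1.0; -0.73 to -0.79 without vehicle replicate 3 or FK506 replicates 1 or 2), lost their calls. Ppfia4 (-1.49) and Ssc4d (-1.44) at day 14 and Prcp (1.97), Timm44 (1.23) and Umod (-0.24) at day 7 did so without any of 5 or 6 single rats, at values from -1.15 to -1.61, 0.84 to 2.02 and -0.21 to -0.24. Day 7 gave 189 higher and 149 lower genes, or 162 in all without FK506 replicate 2, and day 14 gave 132 and 155, or 121 without FK506 replicate 1. The Gapdh ratio at day 7 was 0.437 with FK506 and 0.727 in vehicle, and as a covariate it gave 239 called genes, with Slc12a3 at -1.78, Calb1 at -1.85 and Havcr1 at 2.42.

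After a single dose of FK506 6 mg/kg 3 genes were called, Sec31a of vesicle transport (0.78), Ptgs2 (-1.74) and Cib2 (-0.84). The other probe set of Sec31a was at -0.31 and not called. Each of the 3 genes lost its call when single rats were left out. Those were vehicle replicates 1, 3 or 4 or FK506 replicates 3 or 4 for Sec31a (0.68 to 0.84), vehicle replicates 1 or 4 or FK506 replicates 2 or 3 for Ptgs2 (-1.50 to -1.76) and vehicle replicate 1 or FK506 replicate 3 for Cib2 (-0.63 to -0.80). The distal convoluted tubule list was nevertheless lower, with 0 of 18 members called over all genes and 6 adjusted over the list alone (median -0.21, adjusted p = 5.74e-05 with an estimated correlation). Its members included the calcium channel Trpv5 (-0.64, adjusted p = 0.356), Calb1 (-0.89, adjusted p = 0.24) and Slc12a3 (-0.68, adjusted p = 0.282). Cell cycle genes were higher as a list (0 of 26 called, 5 over the list alone; adjusted p = 0.0331 with an estimated correlation) and fatty acid oxidation genes lower (0 of 21 by either count; adjusted p = 0.0156 with an estimated correlation).

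At FK506 0.6 mg/kg the distal tubule genes were lower from day 7 on and Havcr1 higher from day 14 on. Calb1 changed by -2.07 at day 7, -2.66 at day 14 and -3.52 at day 28 (SE 0.21, adjusted p = 4.18e-26), to 8.63 ± 0.22 (SD, n = 6). Slc12a3 changed by -1.34, -1.54 and -1.23 at these days, and Havcr1 rose by 2.87 at day 14 and 3.12 at day 28 (SE 0.47, adjusted p = 3.15e-06). At day 28 Klk1c9 (2.12), Klk1c4 (1.76), Spp1 (1.51), Clu (1.27) and Timp1 (1.01) were higher, and Cyp2c11 (-2.68), Slc8a1 (-1.42) and Egf (-0.90) lower. Lcn2 (1.64) lost its call without vehicle replicate 5 (1.5), and Urah (-1.33) without any of vehicle replicates 1 to 4 (-1.26 to -1.35). Tubular injury genes rose (9 of 27, 13 over the list alone; adjusted p = 0.0428 with an estimated correlation, and 0.0513 where the tests were adjusted without the array with zeros), distal convoluted tubule genes fell (7 of 18, also over the list alone; 4.05e-07) and ribosomal protein genes rose (20 of 48, 34 over the list alone; 0.0351). At day 7 Glyatl2 (1.17) and Prkaa2, a catalytic subunit of AMP-activated kinase (1.09), were higher. Nmbr (1.13) lost its call without vehicle replicate 1 (0.91), Egf (-0.48) without vehicle replicate 4 or FK506 replicate 2 (-0.45 and -0.43), and Sorcs2 (1.09), Ptgs2 (-1.25) and Slc25a25 (-1.25) without any of at least 4 single rats (0.51 to 1.09, -1.18 to -1.28 and -1.12 to -1.38). At day 14 Rnf41 (1.20), Rbm43 (1.13), Kif23 (0.97), Slc22a13 (-1.72) and Inafm1 (-1.41) lost theirs without any of at least 2 single rats (0.65 to 1.12 and -1.17 to -1.88), Rnf41 at 0.77 without vehicle replicate 2. The counts were 0 at day 1 by limma (373 at an unadjusted p under 0.05), 96 higher and 110 lower at day 7 (54 in all without FK506 replicate 1, 64 with the Gapdh ratio as a covariate), 40 and 53 at day 14 (16 without replicate 3, 61 with that covariate) and 274 and 189 at day 28 (305 without vehicle replicate 2). Between the doses at day 28, 62 genes were higher and 108 lower at 6 mg/kg. Cldn4 (0.84), the chemokine Cxcl10 (0.92), Ndrg4 (0.88), the class II gene RT1-Da (0.82), Slc51a (-1.20), Melk (-0.92) and Acot12 (-0.78) differed, but each lost its call without FK506 6 mg/kg replicates 1, 3, 4 or 5 (0.56 to 0.94 and -0.68 to -1.02), and Aplp1 (-0.84) kept it. The count was 65 without FK506 6 mg/kg replicate 3, 290 without replicate 2, and 17 with the hybridization control level as a covariate.

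**Figure D2:**
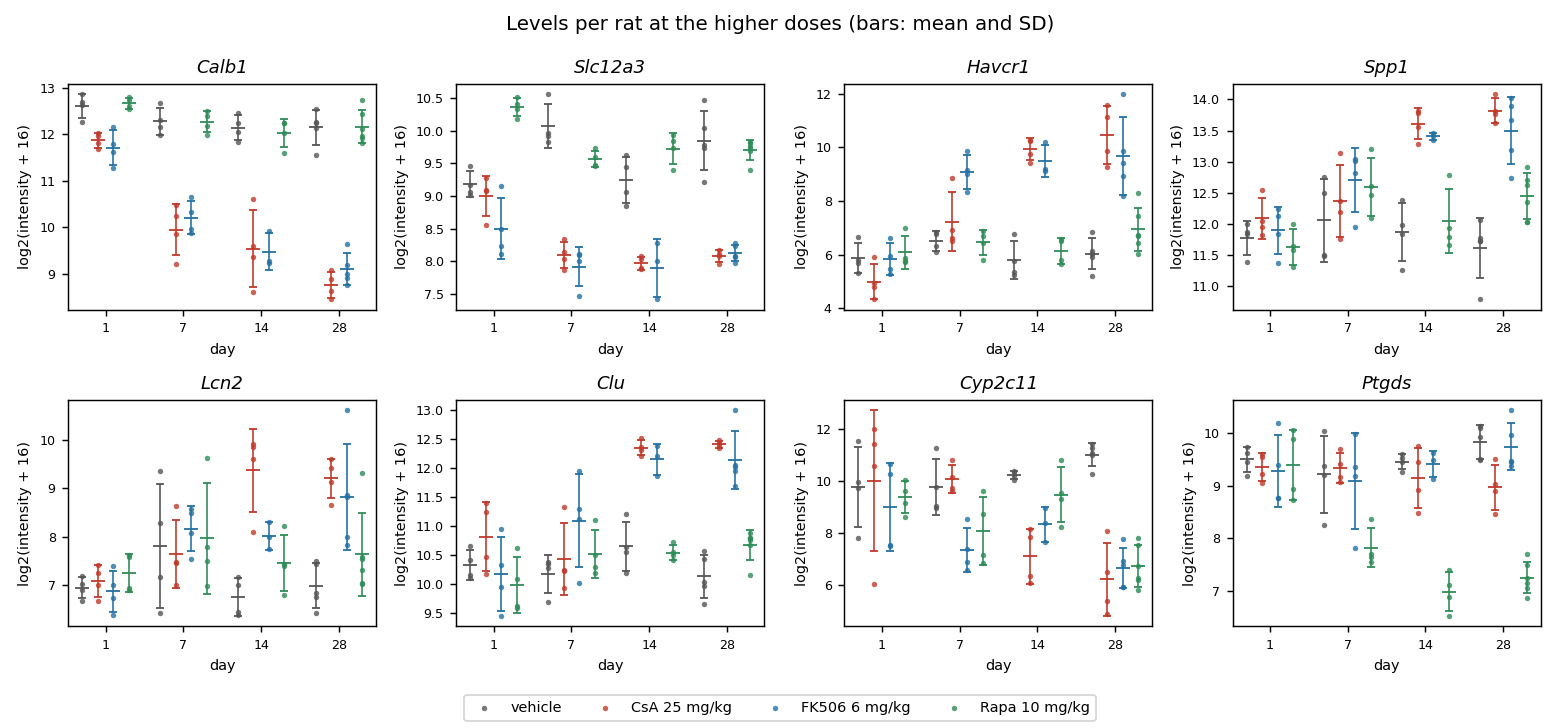
Levels of 8 genes, as log2(intensity + 16), in each rat given vehicle or the higher dose of CsA, FK506 or Rapa, by day. Points are rats, bars mean and SD. At day 28 Calb1 averaged 8.76 with CsA and 9.11 with FK506, against 12.15 in vehicle and 12.17 with Rapa, and Ptgds averaged 7.25 with Rapa against 9.83 in vehicle.

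The responses to CsA and FK506 were compared to find what calcineurin inhibitors share. Of 10663 genes, 611 were higher and 426 lower with both drugs at day 28. Both drugs were set against the same 5 vehicle rats, which adds to what they share. Independent lists of these sizes would share 96.6 and 83.5, and simulated groups with no effect shared means of 3.46 and 0 and at most 203 and 0. With split vehicle rats 183 to 278 genes were higher with both and 139 to 185 lower. Independent lists would then share means of 33.4 and 27.6. A set of 160 higher and 70 lower genes was called for both drugs against vehicle and against Rapa 10 mg/kg, and 186 in all without the array with zeros or 66 with the hybridization control level as a covariate. The largest mean rises in this set were Havcr1 (4.03), Clu (2.15), Spp1 (2.05), Cldn4 (2.03), Adamts1 (1.96), Klk1c9 (1.93), Atf3 (1.93), Gpnmb (1.91), the growth regulator Myc (1.79) and Fblim1 (1.64). The largest mean falls were Calb1 (-3.22), Slc12a3 (-1.74), the organic anion transporter Slco1a1 (-1.71), the calcium-binding Rgn (-1.56), Egf (-1.32), Slc8a1 (-1.29), Gfra1 (-1.10), Tex14 (-0.89), Hspb6 (-0.86) and Wnk1, a kinase that controls Slc12a3 (-0.86). These genes were chosen at day 28, so the groups used there do not test their direction. At day 14, in other treated and vehicle rats, 95% of the higher and 100% of the lower genes had the same sign with CsA 25 mg/kg and 76.2% and 97.1% with FK506 6 mg/kg. At day 7 these shares were 73.1% and 80% for CsA and 66.2% and 78.6% for FK506, and at day 1 65.6% and 84.3%, and 53.8% and 65.7%. The set moved as a whole by fry at days 7 and 14 for both drugs (adjusted p from 2.52e-15 to 0.0384). At day 1 only the lower genes did, with CsA (adjusted p = 0.0063, against 0.157 for the higher genes and 0.761 and 0.101 with FK506). With FK506 0.6 mg/kg the shares of the same sign were 49.4% and 61.4% at day 1, 30% and 72.9% at day 7 and 64.4% and 85.7% at day 14, and only the lower genes moved as a whole at days 7 and 14 (adjusted p = 0.00432 and 1.14e-07, against 0.26 and 0.106 for the higher genes). At day 28 they were 100% and 94.3%, against the vehicle rats by which the set was chosen. Against the same rats CsA 2.5 mg/kg gave 74.4% and 74.3% and Rapa 1 mg/kg 67.5% and 71.4% (adjusted p from 0.108 to 0.145). With Rapa 10 mg/kg the set moved the opposite way at day 7 (28.1% and 31.4%, adjusted p = 0.0151 and 0.0114). The shares were 47.5% and 35.7% at day 1 (0.914 and 0.0818) and 33.8% and 35.7% at day 14 (0.106 and 0.117). At day 7 Rapa 1 mg/kg gave 17.5% and 27.1% (0.00151 and 0.107). The Gapdh ratio was 0.727 in these vehicle rats, 0.391 with Rapa 10 mg/kg and 0.424 with 1 mg/kg. Rapa 10 mg/kg at day 28 helped choose the set and cannot test it.

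**Figure D3:**
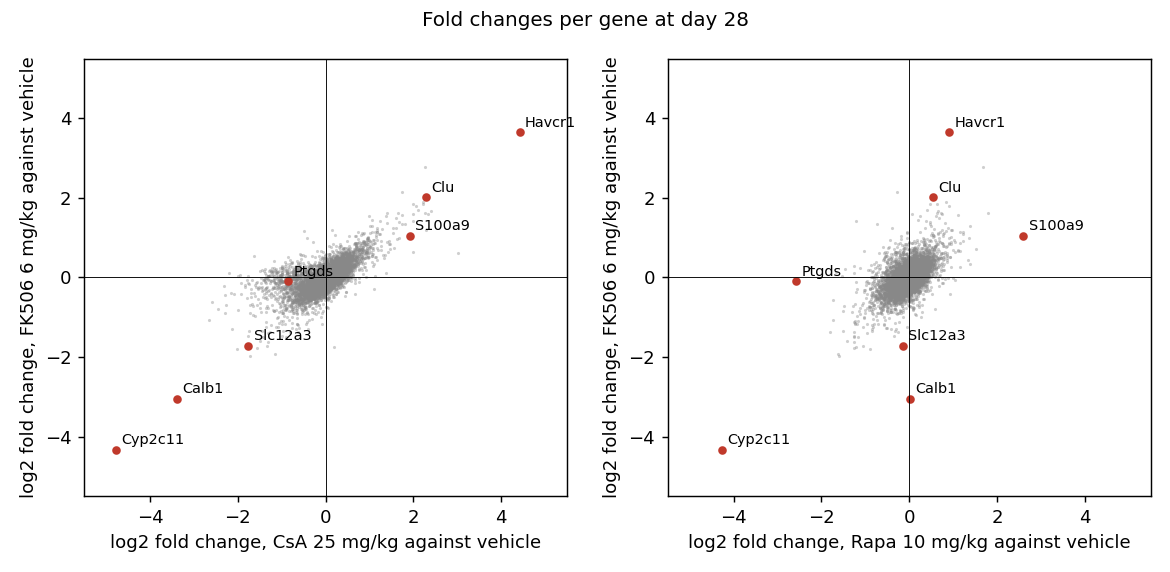
Log2 changes against vehicle at day 28 for each gene, with a few genes in colour. The left panel sets FK506 6 mg/kg (vertical) against CsA 25 mg/kg (horizontal). On the left the correlation across genes was 0.696, and Havcr1 lies at the upper and Cyp2c11 at the lower end of the diagonal.

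Across 10663 genes, which are not independent replicates, the log2 changes with CsA 25 mg/kg and FK506 6 mg/kg correlated at r = 0.359 (Spearman 0.456) at day 1, 0.606 (0.612) at day 7, 0.587 (0.546) at day 14 and 0.696 (0.693) at day 28. Both changes use the same vehicle rats. Simulated groups with no effect, which shared simulated vehicle rats, gave means of 0.474, 0.492, 0.437 and 0.462, and at most 0.845, 0.845, 0.790 and 0.866. Each observed r lay below these highest values, so r with shared vehicle rats does not by itself show a shared effect. The covariance was 0.0166, 0.0369, 0.0492 and 0.0804, against simulated means of 0.0137, 0.0156, 0.0172 and 0.0156 and at most 0.0496, 0.0443, 0.0598 and 0.0491. With split vehicle rats r was 0.072, 0.233, 0.284 and 0.545. CsA and Rapa 10 mg/kg correlated at 0.426 at day 28 (0.290 with split vehicle rats, simulated mean 0.473) and FK506 and Rapa at 0.587 (0.396, simulated mean 0.488). Compared directly at day 28, 224 genes were higher and 381 lower with CsA 25 mg/kg than with FK506 6 mg/kg, and 227 in all without the array with zeros or 62 in a fit to day 28 alone. Slc51a was higher with CsA by 1.93 (SE 0.33, adjusted p = 5.18e-05), Fcgr3a by 1.36 and Mybpc2, a myosin binding protein, by 1.09. Fcgr3a was not called in a fit to day 28 alone or with the hybridization control level as a covariate (1.27). Cxcl13, at 10.58 ± 1.17 (SD, n = 4) with CsA and 8.17 ± 0.40 (SD, n = 5) with FK506, was higher by 2.41, but not called without CsA replicate 4 (1.87). The 4 largest differences in the other direction shrank without the array with zeros, Susd2 from -2.31 to -0.88 (still called, but not in a fit to day 28 alone), Jund from -2.15 to -0.34, Hnf4a from -2.08 to -0.05 and Fgf1 from -1.66 to -0.19. The doses of CsA and FK506 were not matched, so the sizes of their effects are given side by side only.

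Rapa 10 mg/kg after 28 doses was compared with vehicle as the immunosuppressant that does not inhibit calcineurin. Calb1 differed by 0.02 (adjusted p = 0.969), Havcr1 by 0.91 (adjusted p = 0.191). Of 18 distal convoluted tubule genes 1 was higher and 1 lower, also over the list alone, and the list was not called (adjusted p = 0.757). Ptgds (1367851_at), which makes prostaglandin D2, fell by 2.58 (SE 0.27, adjusted p = 7.98e-12), from 9.83 ± 0.32 (SD, n = 5) to 7.25 ± 0.30 (SD, n = 6). Cyp2c11 fell by 4.26 (SE 0.73, adjusted p = 7.08e-06), and the carboxylesterase Ces1e (-1.81), Apcs, serum amyloid P (-1.74), the neurofilament Nefm (-1.73), Mmp9 (-1.67), Gcgr (-1.63), Cyp8b1 (-1.59), tetranectin Clec3b (-1.54) and Dusp15 (-1.51) were lower. The fibrillar collagens Col1a1 (-1.25, adjusted p = 0.000134) and Col3a1 (-0.80) were lower too. The myeloid calcium-binding S100a9 rose by 2.60 (SE 0.54, adjusted p = 0.000204), to 8.57 ± 1.27 (SD, n = 6), Igfbp1 by 1.80, the acute-phase Saa3 by 1.52, Ccdc127 by 1.40, Wfdc10a by 1.36, Alas2 of erythroid heme synthesis by 1.34, the chemokine Ccl6 by 1.24, Scara5 by 1.24, the proteoglycan Vcan by 1.22 and the sulfotransferase Sult1a1 by 1.17. Of 48 ribosomal protein genes 38 rose (40 over the list alone; adjusted p = 0.0096 with an estimated correlation), such as Rps15a (0.52) and Rps6 (0.39). Fatty acid oxidation genes were lower (11 of 21, 14 over the list alone; adjusted p = 0.0496 with an estimated correlation, and 0.0626 where the tests were adjusted without the array with zeros), as in Cyp4a1 (-0.77) and Ehhadh (-0.71), and so were those of gluconeogenesis and glycolysis (6 of 17, 1 higher, also over the list alone; 0.00465), as in Pc, pyruvate carboxylase (-0.75), and Pfkl (-0.60). Spp1 (0.83) lost its call without vehicle replicate 2 (0.63), and the proliferation marker Mki67 (-0.63) and the calcineurin target Rcan1 (-0.42) without vehicle replicates 2, 4 or 5 (-0.50 to -0.64 and -0.33 to -0.44). The other probe sets of Vcan (0.39 and 0.12) and Clec3b (-0.68) were not called, nor was Dusp15 in a fit to day 28 alone. There were 813 higher and 870 lower genes, 65 of them changed by more than 2-fold.

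With Rapa 10 mg/kg cell cycle genes were lower at day 7, and Ptgds, Col1a1 and Col3a1 at day 14. At day 7, 13 of 26 cell cycle genes fell (14 over the list alone; adjusted p = 0.00768 with an estimated correlation), among them Top2a (-1.90), Kif20a (-1.89) and Mki67 (-1.71). Slfn4 (-2.15), Klk1c9 (-2.05) and the antiviral helicase Ddx60 (-2.00) were lower, and the transporter Slc7a12 (1.34), Glyatl2 (1.23) and Zbtb41 (1.16) higher. Of 22 interferon response genes 10 were lower (13 over the list alone), such as Isg15 (-1.66) and Usp18 (-1.63), but the list lost its call with an estimated correlation (adjusted p = 0.117). At day 14 Ptgds changed by -2.48, Klk1c4 by -2.30, Mmp9 by -1.97, the alcohol dehydrogenase Adh1c by -1.97, Col1a1 by -1.34, Col3a1 by -1.20 and Mki67 by -1.20, and Rnf41 rose by 1.62 and S100g, a calcium-binding protein, by 1.49. The 2 other probe sets of Rnf41 (0.43 and 0.24) were not called, nor was that of Mmp9 (-1.09, adjusted p = 0.0501). Of 30 extracellular matrix genes 12 were lower and 2 higher at day 14 (14 and 4 over the list alone), but the list lost its call with an estimated correlation (adjusted p = 0.488). Ribosomal protein genes rose (26 of 48, 32 over the list alone; adjusted p = 0.0379 with an estimated correlation) and gluconeogenesis and glycolysis genes fell (4 of 17, also over the list alone; 0.0324). Igfbp1 (1.64), Wfdc10a (1.5) and Rcan1 (-0.58) at day 14 lost their calls without any of at least 4 single rats (1.39 to 1.67, 1.12 to 1.35 and -0.45 to -0.56). At day 7 Hsd17b1 (-1.94) lost its call without Rapa replicate 3 (-1.49), and Adam9 (1.35) with the Gapdh ratio as a covariate (0.64). The Gapdh ratio at day 7 was 0.391 with Rapa 10 mg/kg and 0.727 in vehicle. With that covariate 564 genes were called and Mki67 was at -1.43. Cell cycle genes were called as a list by the preset correlation alone, which decides little. Day 7 gave 323 higher and 458 lower genes, or 444 in all without Rapa replicate 2, and day 14 gave 554 and 557, or 736 without Rapa replicate 3.

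A single dose of Rapa 10 mg/kg gave 180 higher and 120 lower genes. Foxp4 (1.49), Scaf1 (1.39), Igfbp4 (1.36) and Slc12a3 (1.18) were higher, and the zinc transporter Slc39a5 (-1.87), Impa2 (-1.52), Adam9 (-1.36) and A1cf (-1.14) lower. Rapa 1 mg/kg gave 210 and 119 at that day, with Foxp4 (1.65), Scaf1 (1.27), Slc12a3 (1.19), Igfbp4 (1.12), Adam9 (-1.60) and Prkaa2 (-1.28) moved alike. Against the same vehicle rats 107 genes were higher with both doses, and 19 to 24 with each dose set against a different part of those rats. Both groups had a high 3-prime to 5-prime Gapdh ratio on the log2 scale, at 0.739 for 10 mg/kg and 0.674 for 1 mg/kg. Vehicle and CsA 2.5 mg/kg at day 7 were also high (0.727 and 0.791), and all other groups lay between 0.267 and 0.476. With this ratio as a covariate 7 genes were called for 10 mg/kg and 45 for 1 mg/kg. The count for 10 mg/kg was 199 without Rapa replicate 3. Scaf1 kept its call at both doses, while at 10 mg/kg Foxp4 (0.99), Igfbp4 (0.89), Slc12a3 (0.67), Slc39a5 (-0.66), Impa2 (-1.36), Adam9 (-0.48) and A1cf (-0.76) did not. At 1 mg/kg Foxp4 (1.23), Igfbp4 (0.72) and Adam9 (-0.87) also lost theirs. Fatty acid oxidation genes were lower at 10 mg/kg (5 of 21, 11 over the list alone; adjusted p = 0.00332 with an estimated correlation), with Acot2 at -0.55. Atg10 (1.52) at the higher dose and Chrna2 (-1.17) at the lower lost their calls without single rats, at 1.38 to 1.54 and -0.74 to -1.15, and Foxp4 at 10 mg/kg without Rapa replicate 2 (1.42).

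**Figure D4:**
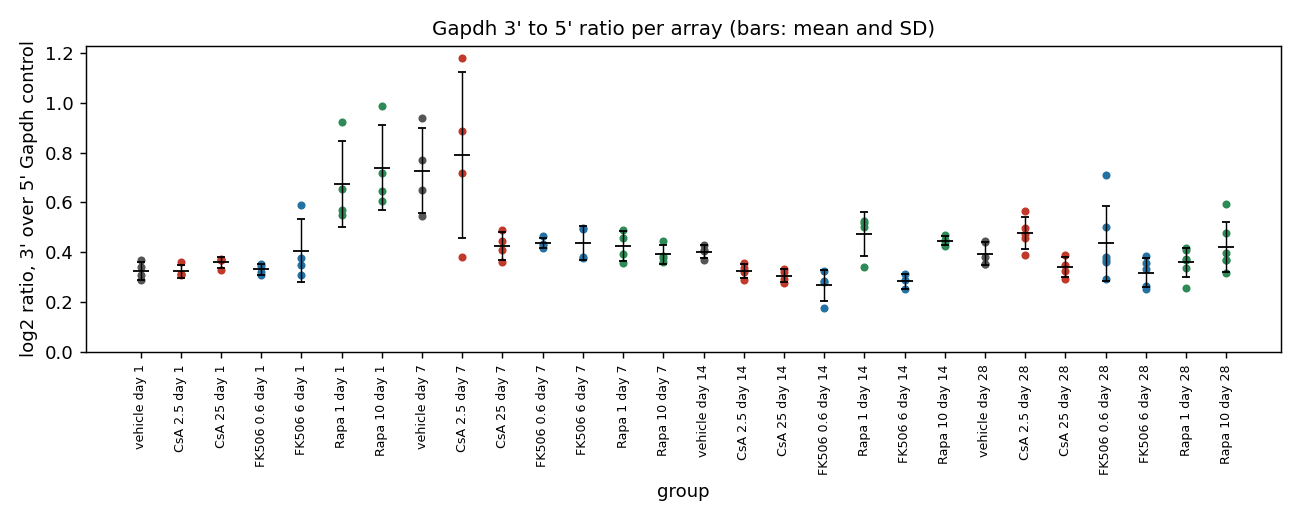
Log2 ratio of the 3-prime to the 5-prime Gapdh probe set for each array, by group. Points are rats, bars mean and SD. Rapa at day 1 (means 0.674 and 0.739) and vehicle and CsA 2.5 mg/kg at day 7 (0.727 and 0.791) lie above the other groups.

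Rapa 1 mg/kg shared 375 of its 498 higher genes and 399 of its 546 lower genes at day 28 with the higher dose, both set against the same 5 vehicle rats. Independent lists would share 38.0 and 44.5, and simulated groups with no effect shared at most 333 and 5. With split vehicle rats 55 to 136 and 64 to 138 were shared, where independent lists would share means of 7.75 and 9.07. At day 28 Ptgds fell by 2.75 (SE 0.27, adjusted p = 1.11e-12), Ces1e changed by -2.10, Cyp8b1 by -1.64, Col1a1 by -1.16, Col3a1 by -0.96 and Rcan1 by -0.60, and S100a9 rose by 2.16, Cdk5rap3 by 1.39 and Ccl6 by 1.38. S100a9 was not called in a fit to day 28 alone. Cyp2c11 (-2.95) lost its call with the hybridization control level, which was 9.94 ± 1.16 (SD, n = 6) here, as a covariate (-2.32). Without replicate 4 of this group, which lay far from its other rats in several markers, Igfbp1 (1.51, then 1.14), Lcn2 (1.34, then 0.77), Spp1 (0.97, then 0.70), Clu (0.77, then 0.56) and Vim (0.50, then 0.29) were no longer called, and some of them ended without single vehicle rats too (Spp1 0.76 and Clu 0.65 at the lowest). At day 7 cell cycle genes were lower (14 of 26, 15 over the list alone; adjusted p = 0.0018 with an estimated correlation), among them Cdkn3 (-1.75), Ccnb2 (-1.72) and Mki67 (-1.58), and at day 14 Ptgds (-2.34), Dpp7 (-1.81), Dgkg (-1.79) and Apcs (-1.64) were lower and Rasd1 (1.74) higher. Col1a1 at day 14 (-1.22) lost its call without vehicle replicate 3 (-0.88), and S100a9 (2.10), Igfbp1 (1.76), Wfdc10a (1.68) and Mki67 (-0.83) without any of 3 or 4 single rats, S100a9 at 1.51 without Rapa replicate 2. Lists called at day 28 with an estimated correlation were ribosomal proteins (29 of 48 higher, 37 over the list alone; adjusted p = 0.0165) and fatty acid oxidation (12 of 21 lower, 14 over the list alone; 0.025). Counts were 172 higher and 277 lower at day 7 (221 in all without Rapa replicate 1, 214 with the Gapdh ratio as a covariate), 435 and 532 at day 14 (574 without Rapa replicate 4), 498 and 546 at day 28, and at day 1 176 without vehicle replicate 3. Between the doses at day 28, 4 genes were higher and 9 lower at 10 mg/kg, and 5 were called in all without replicate 4 of 1 mg/kg. The sterol enzyme Dhcr7 (-0.87) kept its call there, while the receptor Kit (-0.85), Prepl (0.39), Tdrd7 (0.33), Pum2 (0.25), Slc17a5 (-0.38) and Hcfc1r1 (-0.36) did not (-0.83, 0.38, 0.32, 0.24, -0.35 and -0.38), and 0 of the 13 were called by limma in a fit to day 28 alone.

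FK506 and Rapa, both macrolides that bind FKBP12, were compared directly, at doses that differ. At day 28 Calb1 was lower with FK506 6 mg/kg than with Rapa 10 mg/kg, at -3.06 (95% interval -3.48 to -2.65), and so were Slc12a3 (-1.58, -1.91 to -1.25), Egf (-1.13, -1.32 to -0.93) and S100g (-1.35). Havcr1 was higher with FK506 by 2.73 (1.80 to 3.67), Klk1c4 by 2.64, Ptgds by 2.49 (1.95 to 3.03), Klk1c9 by 2.41, Clu by 1.46, Col1a1 by 1.38 (0.87 to 1.88) and Spp1 by 1.06 (0.50 to 1.61). No difference was called for Cyp2c11 (-0.08, -1.52 to 1.37), Lcn2 (1.19, 0.31 to 2.07, adjusted p = 0.0699), Rcan1 (0.10, -0.21 to 0.40), the phosphate transporter Slc34a1 (0.02, -0.07 to 0.11) or the water channel Aqp2 (-0.01, -0.46 to 0.44). Over all genes 712 were higher and 451 lower with FK506, or 372 in all with the hybridization control level as a covariate, and for 10177 of 10663 the interval excluded a difference of 1 or more in either direction. At 0.6 and 1 mg/kg the differences at day 28 were -3.34 for Calb1 (-3.74 to -2.94), -1.13 for Slc12a3 (-1.45 to -0.82), 1.82 for Havcr1 (0.93 to 2.71), 2.62 for Ptgds (2.10 to 3.13), 2.65 for Klk1c9, 2.51 for Klk1c4, -1.20 for Slc8a1 and -1.43 for Slc7a12, with 544 higher and 316 lower genes. Havcr1 was not called there in a fit to day 28 alone. At day 14 Klk1c4 was higher with FK506 by 4.09, Havcr1 by 3.36 and Klk1c9 by 2.59, and Calb1 (-2.55), Ptgs2 (-2.11), Sfrp2, a Wnt antagonist (-1.97), and Slc12a3 (-1.82) were lower. At day 7 Klk1c9 (2.85), Klk1c4 (2.76) and Havcr1 (2.63) were higher and Ptgs2 (-2.51), Calb1 (-2.07), Slc12a3 (-1.64) and C2h3orf80 (-1.52) lower. Heme oxygenase Hmox1 lost its call without any of at least 4 single rats at day 7 (2.97, then 2.56 to 2.95) and day 14 (2.74, then 1.94 to 2.90), and Eri2 at day 28 (-1.38) without FK506 replicates 1, 2, 3 or 5 (-1.14 to -1.45). At day 1 the proliferation genes Cdca3 (1.25) and Mki67 (1.26; 1.08 and no call without FK506 replicate 3) were higher with FK506 and Slc12a3 (-1.86), Igfbp4 (-1.27) and Ptgs2 (-1.57; -1.38 and no call without Rapa replicate 4) lower. Adam9 (1.13) and Mgat3 (1.11) were not called there with the Gapdh ratio as a covariate (0.42 and 0.54). Counts were 91 and 83 at day 1 (50 in all without FK506 replicate 2, 61 with the Gapdh ratio as a covariate), 435 and 251 at day 7 (398 without Rapa replicate 2) and 515 and 497 at day 14 (475 without FK506 replicate 1).

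Some genes changed with all 3 drugs at the higher dose and day 28, 261 higher and 221 lower, where 7.37 and 6.81 would be shared by independent lists. All 3 comparisons used the same 5 vehicle rats, too few to split 3 ways, and part of the excess may come from them. Simulated groups with no effect that shared them gave 0 genes in either direction. Cyp2c11 changed by -4.78, -4.33 and -4.26 with CsA, FK506 and Rapa, Cyp8b1 by -1.73, -1.97 and -1.59, Gcgr by -1.16, -1.92 and -1.63, the prolactin receptor Prlr by -1.77, -1.48 and -1.25 and pyruvate kinase Pklr by -1.43, -1.50 and -1.26. Igfbp1 rose by 1.40, 1.62 and 1.80 and Myc by 1.98, 1.60 and 0.75.

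How far each effect differed between day 28 and day 1 was tested as an interaction at the higher doses. For CsA Havcr1 had risen more at day 28, by 5.29 (SE 0.75, adjusted p = 9.16e-07), Cldn4 by 2.60, Pilra by 2.40 and Adamts1 by 2.29. Cyp2c11 (-5.02), Alb (-5.67), Serpina1 (-4.11) and Ttr (-3.90) differed in the other direction, and without the arrays with Alb above 12 these 4 were at -3.33, -1.30, -0.03 and -0.03 and not called. Alb, Serpina1 and Ttr also lost their calls without replicate 3 (-4.19, -2.73 and -2.59) or replicate 4 (-4.23, -2.76 and -2.63) of CsA 25 mg/kg at day 1. For FK506 Havcr1 (3.67), Clu (2.17) and Fblim1 (1.92) had risen more at day 28 and Calb1 (-2.15, adjusted p = 1.69e-05), Cyp8b1 (-2.09) and Gcgr (-1.96) had fallen more. For Rapa Ccdc127 (2.30), Eml2 (2.21), Arhgap5 (1.77) and Nipbl (1.72) were relatively higher and Ptgds (-2.48, adjusted p = 2.68e-05) lower. The 3 other probe sets of Nipbl (0.01 to 0.21) were not called. Arhgap5 lost its call with an offset of 1 (1.83), in a fit to days 1 and 28 alone (1.77) and with the Gapdh ratio as a covariate (1.61). Cdk5rap3 (1.98) and Atg10 (-2.06) with FK506 and Atg10 (-1.87), Slc22a13 (-1.96) and Cyp2c11 (-3.87) with Rapa lost their calls without any of at least 2 single rats (1.72 to 1.86, -1.75 to -1.99, -1.69 to -1.89, -1.81 to -1.96 and -3.22 to -3.64). The counts were 302 and 223 for CsA (353 in all without replicate 3 of day 1, 986 without replicate 1 of day 28), 198 and 155 for FK506 (218 without replicate 4 of day 1) and 233 and 355 for Rapa (171 with the Gapdh ratio as a covariate). The hybridization control level as a covariate gave 85 for FK506 and ended the calls of Cyp8b1 (-2.03) and Gcgr (-1.69). Vehicle rats themselves differed between day 28 and day 1, with 96 genes higher and 126 lower, or 87 in all without vehicle replicate 4 of day 1. Csf2rb, a cytokine receptor, was higher by 0.98, and the erythroid genes Alas2 (-1.37) and Hbb (-1.35) were lower. Map3k6 (1.13), Nefm (1.13), Kcnip1 (1.06), Alox15 (-1.43) and Cdk5rap3 (-1.42) lost their calls without any of at least 2 single vehicle rats, at 0.73 to 1.10, 1.04 to 1.07, 0.86 to 1.10, -1.25 to -1.41 and -1.16 to -1.45.

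Over the 36 lists and 24 comparisons with vehicle, 172 of 864 tests were called with the preset correlation and 47 of these also with an estimated correlation, whose median was 0.111. By fry, which asks whether the genes of a list move on balance in 1 direction, 157 were called, 123 of them among the 172. The distal convoluted tubule list, with Calb1 and Slc12a3 among its members, was lower with an estimated correlation in all 4 comparisons of CsA 25 mg/kg and all 4 of FK506 6 mg/kg. FK506 0.6 mg/kg gave the same call at days 7, 14 and 28 (5, 5 and 7 of 18 members lower, and 5, 8 and 7 adjusted over the list alone; adjusted p = 0.00332, 1.45e-06 and 4.05e-07). No Rapa comparison gave it, though with Rapa 1 mg/kg Slc12a3 was called at days 7 (-0.63) and 14 (0.59), calls that ended without any of 5 single rats (-0.47 to -0.66 and 0.46 to 0.57). Ribosomal protein genes such as Rps15a were higher with an estimated correlation at day 28 in all higher-dose groups and in FK506 0.6 mg/kg and Rapa 1 mg/kg. At day 7 their smaller rises were called with the preset correlation, but not without quantile normalization (adjusted p = 0.944 for CsA 25 mg/kg, 0.784 for FK506 6 mg/kg, where the direction turned, and 0.647 for Rapa 10 mg/kg).

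**Figure D5:**
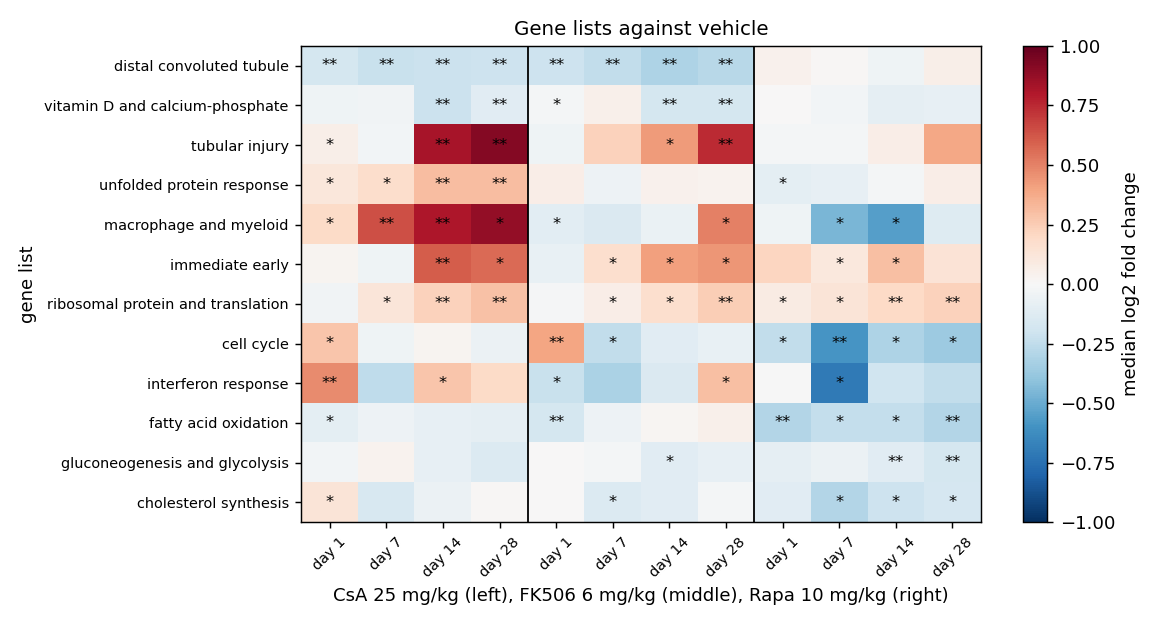
Median log2 change of the measured members of 12 fixed gene lists (vertical axis) against vehicle at each day (horizontal axis) for CsA 25, FK506 6 and Rapa 10 mg/kg. A single star is a list called with the preset correlation only and a double star also with the estimated correlation. The distal convoluted tubule list is blue with a double star in all 8 CsA and FK506 columns, and the tubular injury list reached medians of 0.92 with CsA and 0.75 with FK506 at day 28.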

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

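The tests of RNA quality for Rapa at day 1, of the array with zeros for CsA against FK506, and of both explanations for CsA 25 mg/kg at day 1 were chosen only after those results were seen. Among 19 marker genes in the 7 groups of day 28 (133 sets of rats), 12 values, in 9 rats, lay apart from the others of their group by Dixon's test, and among 3 array measures (81 sets) 9 values, in 8 arrays, did. Chance gives about 1 in 20.

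At a single dose Rapa 10 mg/kg gave 300 called genes, Slc12a3 and Igfbp4 among them, in a group whose arrays had a higher Gapdh 3-prime to 5-prime ratio than vehicle, by 0.413 on the log2 scale. The slopes of genes on this ratio within groups of the other days predicted the sign of 88% of the called genes, against 58.6% of all genes, and a median of 0.307 of the observed change. With the ratio as a covariate 7 genes were called, the median absolute change of the 300 went from 0.459 to 0.311 and the median SE from 0.114 to 0.126, so that smaller changes more than wider errors ended the calls. The tables argue against an effect of Rapa that holds from day 1 on as the whole cause, since 75.7% of the 300 genes had the same sign at day 14 but 50.7% at day 28. A difference in RNA quality or labelling is a candidate explanation for part of the pattern, and an effect of Rapa that passes by day 28 was not tested.

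In CsA 25 mg/kg at day 28, replicate 3 was the array with all zeros, the lowest median intensity (52.0, with its group at 72.6 to 76.4) and the lowest correlation with its group (0.870, with the others at 0.940 to 0.944). The tables argue against this array as the whole cause of the count against vehicle, which was 2255 with it and 1685 without it. It may account for most of the difference between CsA and FK506, since 605 genes were called with it and 227 without it, and for the size of 8 named falls against vehicle, such as Slc22a12 (-2.65 and -1.01) and Hnf4a (-2.31 and -0.28). Havcr1 (4.42 and 4.20) and Calb1 (-3.39 and -3.35) barely moved. Against vehicle the other probe sets gave -0.36 and -0.59 for Hnf4a, -0.41 for Susd2 and 0.15 for Eri2, but -2.16 and -2.14 for Afmid. Against FK506 those of Hnf4a, Susd2, Jund and Fgf1 lay from -0.24 to 0.11 and none was called. These are the genes with the largest falls, so whether the array was processed in another way by the authors or came from a rat with a stronger response stays open.

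In CsA 25 mg/kg at day 1 the arrays of replicates 3 and 4 held Alb at 14.38 and 14.49, against 4.60 to 6.61 in the other 6 rats. From a list of 41 liver markers, 21 were measured, and 81% of these lay at least 1 log2 above all 6 other rats in both arrays, which is consistent with RNA from liver in the 2 samples. Of the 21, 8 lay above the median gene in vehicle kidneys at day 1, and 16 of the 66 risen genes were on the list. The tables argue against an effect of CsA in every treated rat as the whole cause, since 34.8% of the risen genes kept at least 25% of their log2 change without the 4 arrays of the series with Alb above 12. Kidney markers in these arrays were close to those of the other rats (Umod 13.65 and 13.79, against 13.58 to 13.71, and Slc34a1 13.61 and 13.62, against 13.70 to 13.79), and the route by which such RNA could enter, in 2 rats or in their samples, stays open.

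Rats far from the others of their group at day 28 were, in vehicle, replicate 2 with Spp1 at 10.78 (others 11.72 to 12.06) and Kl at 5.93 (6.58 to 6.72). In CsA 25 mg/kg, replicate 4 had Vim at 11.28 (10.23 to 10.29). In FK506 0.6 mg/kg, replicate 5 had Havcr1 at 10.81 (8.38 to 9.15). In FK506 6 mg/kg, replicate 3 had Clu at 13.00 (11.69 to 12.06) and replicate 5 Cyp27b1 at 8.32 (6.86 to 7.23). In Rapa 1 mg/kg, replicate 4 had Lcn2 at 11.15 (7.42 to 8.23), Vim at 11.31 (9.74 to 10.25) and a mean correlation with its group of 0.968 (0.975 to 0.978), and replicate 1 had Kl at 5.44 (6.46 to 6.84). In Rapa 10 mg/kg, replicate 4 had Slc12a3 at 9.40 (9.69 to 9.83) and Clu at 10.16 (10.67 to 10.89), replicate 6 Lcn2 at 9.32 (7.02 to 7.58) and replicate 3 a median intensity of 69.9 (73.5 to 75.4). At other days the Gapdh ratio stood apart in replicate 4 of CsA 2.5 mg/kg at day 1 (0.36, others 0.31), replicate 4 of CsA 25 mg/kg at day 1 (0.33, others 0.37) and replicate 1 of Rapa 1 mg/kg at day 14 (0.34, others 0.50 to 0.53). Replicate 1 of Rapa 10 mg/kg at day 7 had a mean correlation of 0.977 (others 0.974), and replicate 1 of CsA 25 mg/kg at day 14 a median intensity of 78.5 (73.0 to 73.9).

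The effect against vehicle differed between day 28 and day 1, by a test of the interaction, for 525 genes with CsA 25 mg/kg, 353 with FK506 6 mg/kg and 588 with Rapa 10 mg/kg. Probe sets with no gene symbol, which no comparison above uses, were called at day 28 as well, 869 of 6393 with CsA 25 mg/kg, 446 with FK506 6 mg/kg and 394 with Rapa 10 mg/kg.

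Chance as the source of the counts was tested with other splits of the same rats into groups of the same sizes, 35 at days 1 to 14 and 100 elsewhere. A real count of 0 is met by every split, so the test says nothing for CsA 2.5 mg/kg at day 1 (35 of 35 splits; highest other 1), day 7 (35 of 35; 197) and day 28 (100 of 100; 1) or for FK506 0.6 mg/kg at day 1 (35 of 35; 2). Chance could not be excluded for CsA 2.5 mg/kg at day 14 (4 of 35; real count 7, highest other 21) or for the dose contrast of Rapa (7 of 100; 13 and 149). A split of the vehicle and CsA 2.5 mg/kg rats of day 7 that gave 197 genes, and a split of the Rapa rats of day 28 that gave 149, point to a structure of the samples apart from the groups. Chance stays open for CsA 25 mg/kg against FK506 6 mg/kg (2 of 100, 605 and 776) and the dose contrast of FK506 (2, 170 and 179). So it does for the interactions for CsA (2, 525 and 822) and FK506 (2, 353 and 358), as in all 4 another split gave more genes. In all other comparisons the real split alone gave as many genes (1 of 35 or 1 of 100). The real count and the highest other were, for days 1, 7, 14 and 28, 72 and 62, 428 and 154, 841 and 33, and 2255 and 1371 with CsA 25 mg/kg. They were 3 and 1, 338 and 70, 287 and 100, and 1704 and 558 with FK506 6 mg/kg, and 206 and 198, 93 and 15, and 463 and 16 from day 7 on with FK506 0.6 mg/kg. For Rapa 1 mg/kg they were 329 and 1, 449 and 146, 967 and 340, and 1044 and 901, and for Rapa 10 mg/kg 300 and 5, 781 and 135, 1111 and 49, and 1683 and 1135. For FK506 6 mg/kg against Rapa 10 mg/kg they were 174 and 22, 686 and 30, 1012 and 304, and 1163 and 675, and for the lower doses at day 28 860 and 282. For the dose contrast of CsA they were 1962 and 1140, for the Rapa interaction 588 and 123, for vehicle at day 28 against day 1 222 and 54, and for the genes shared by both calcineurin inhibitors 230 and 2. With the rats of each day dealt to the groups at random, the preset correlation called a median of 98 lists and at most 172, as many as the real 172 (2 of 100), while the estimated correlation called at most 2, against 47 (1 of 100).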

How the results depend on the processing

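The alternatives with the Gapdh ratio, the hybridization controls, the arrays with high Alb, the array with zeros or replicate 4 of Rapa 1 mg/kg at day 28 were chosen only after the results were seen. No named gene was called in the opposite direction under any alternative run. Of the called lists only ribosomal protein genes for FK506 6 mg/kg at day 7 changed sign, without quantile normalization, and were then not called (adjusted p = 0.784). Named genes kept their direction and side of the threshold in 704 of 712 cases with an offset of 1, 711 of 718 with an intensity trend, 697 without quantile normalization, 696 without the filter on dim genes, 694 with all probe sets, 699 without the arrays with high Alb, 682 with the hybridization controls, 677 with the Gapdh ratio and 641 with the compared days alone. They did so in 5303 of 5669 cases with a rat left out, and 354 of the others lost their call. Of 55 other probe sets of called named genes, 48 had the same sign and 18 were also called, and 0 were called in the opposite direction. Genes called under neither setting counted as unchanged, whatever their sign. Of 172 list calls with the preset correlation, 171 were kept without the array with zeros, 167 without the arrays with high Alb, 163 with the Gapdh ratio, 160 without quantile normalization, 123 by fry and 47 with an estimated correlation. Arrays limit what can be seen by signal over background, and 3554 dim genes were left out. In simulated groups of the sizes of CsA 25 mg/kg, FK506 6 mg/kg and Rapa 10 mg/kg at day 28, changes of 1 log2 were called in 93.8%, 96.7% and 91.1% of genes and changes of 0.5 log2 in 67.1%, 62.1% and 68.3%, where the median called change was 0.474, 0.396 and 0.367. The cause was not tested for the counts below. A fit to fewer arrays also changes the estimate of the spread, and a fit to other genes the number of tests.

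Counts that moved by more than 1.5 times are given by setting. With the Gapdh ratio as a covariate they were 1 for CsA 2.5 mg/kg at day 7, 64 and 61 for FK506 0.6 mg/kg at days 7 and 14, 45 and 214 for Rapa 1 mg/kg at days 1 and 7, 7 for Rapa 10 mg/kg at day 1, 61 for FK506 6 mg/kg against Rapa 10 mg/kg at day 1, 8 for Rapa 10 against 1 mg/kg and 171 for the Rapa interaction. With the hybridization controls they were 727 for FK506 6 mg/kg and 583 for Rapa 1 mg/kg at day 28, 372 for FK506 6 against Rapa 10 mg/kg at day 28, 85 for CsA against FK506, 17 for FK506 6 against 0.6 mg/kg, 0 by limma for Rapa 10 against 1 mg/kg, 85 for the FK506 interaction and 66 for the calcineurin inhibitor genes. Without quantile normalization they were 2 for CsA 2.5 mg/kg at day 14, 257 for FK506 6 against 0.6 mg/kg and 1 for Rapa 10 against 1 mg/kg. With all probe sets, which changes the number of tests, they were 14 for CsA 2.5 mg/kg at day 14, 134, 645 and 3828 for CsA 25 mg/kg at days 1, 7 and 28, 377 and 157 for FK506 0.6 mg/kg at days 7 and 14, 524 for FK506 6 mg/kg at day 7, 670 and 852 for Rapa 1 mg/kg at days 1 and 7, and 729, 1272 and 1689 for Rapa 10 mg/kg at days 1, 7 and 14. They were also 280 for FK506 6 against Rapa 10 mg/kg at day 1, 1244 for CsA against FK506, 3181 for CsA 25 against 2.5 mg/kg, 0 by limma for Rapa 10 against 1 mg/kg, 1021 for the Rapa interaction and 355 for vehicle day 28 against day 1. With the compared days alone, and so fewer arrays, they were 0 by limma for CsA 2.5 mg/kg at day 14, 1 for CsA 25 mg/kg at day 1, 100, 15 and 213 for FK506 0.6 mg/kg at days 7, 14 and 28, 8, 174 and 158 for FK506 6 mg/kg at days 1, 7 and 14, 267 and 637 for Rapa 1 mg/kg at days 7 and 28, and 525 for FK506 0.6 against Rapa 1 mg/kg. They were 62 for CsA against FK506, 1169 for CsA 25 against 2.5 mg/kg, 11 for FK506 6 against 0.6 mg/kg, 0 for Rapa 10 against 1 mg/kg and 130 for the calcineurin inhibitor genes. Without the arrays with high Alb they were 4 for CsA 2.5 mg/kg at day 14, 5 for CsA 25 mg/kg at day 1 and 208 for the CsA interaction. Others were 4 for CsA 2.5 mg/kg at day 14 with an intensity trend, 182 for CsA 25 mg/kg at day 1 and 1 for Rapa 10 against 1 mg/kg without the filter on dim genes, and 90 calcineurin inhibitor genes at a limit of 0.01. The correlation of CsA with FK506 was 0.072, 0.233, 0.284 and 0.545 at days 1, 7, 14 and 28 with split vehicle rats. The share of called genes that were higher moved without quantile normalization from 37% to 26.9% for CsA against FK506.

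With each rat left out in turn, counts ran from 0 to 1, 0 to 11 and 0 to 13 for CsA 2.5 mg/kg at days 1, 7 and 14, from 6 to 119 and 239 to 492 for CsA 25 mg/kg at days 1 and 7, from 54 to 245, 16 to 93 and 305 to 435 for FK506 0.6 mg/kg at days 7, 14 and 28, and from 0 to 6, 162 to 383 and 121 to 282 for FK506 6 mg/kg at days 1, 7 and 14. They ran from 176 to 248, 221 to 429 and 574 to 993 for Rapa 1 mg/kg and from 199 to 250, 444 to 701 and 736 to 1110 for Rapa 10 mg/kg at the same days. Other ranges were 50 to 284, 398 to 647 and 475 to 1002 for FK506 6 against Rapa 10 mg/kg at days 1, 7 and 14, 227 to 787 for CsA against FK506, 65 to 290 for FK506 6 against 0.6 mg/kg, 353 to 986 and 218 to 403 for the CsA and FK506 interactions and 87 to 190 for vehicle day 28 against day 1. Rapa 10 against 1 mg/kg gave 5 without Rapa 1 mg/kg replicate 4. Without the array with zeros the correlation of CsA with FK506 at day 28 was 0.790.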

Other observations

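The test of a halted rise of Cyp2c11 with age as the whole cause of its fall, and the count without arrays with high Alb, were chosen only after the result was seen. Ptgs2, which encodes cyclooxygenase-2, was called lower with CsA 25 mg/kg at days 1 and 14 (-1.48 and -1.17), with FK506 6 mg/kg at days 1, 7 and 28 (-1.74, -1.66 and -0.98), with FK506 0.6 mg/kg at days 7 and 28 (-1.25 and -1.15) and in no comparison of Rapa with vehicle. Both day 1 calls and that of FK506 0.6 mg/kg at day 7 ended without any of at least 4 single rats (-1.18 to -1.76). Its group means were chosen for this account after they were seen. At day 7 Ptgs2 stood at 7.41 ± 0.12 (SD, n = 4) in vehicle, 6.42 ± 0.21 with CsA 25 mg/kg, 6.15 ± 0.22 with FK506 0.6 mg/kg, 5.75 ± 0.35 with FK506 6 mg/kg and 8.26 ± 0.42 with Rapa 10 mg/kg. The direct test of FK506 6 mg/kg against Rapa 10 mg/kg gave -2.51 at day 7 (adjusted p = 2.01e-07) and -2.11 at day 14 (adjusted p = 3.85e-05).

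At day 28 Hbb, a haemoglobin gene, rose by 1.17 and Alas2 by 1.34 with Rapa 10 mg/kg and by 1.02 and 0.94 with 1 mg/kg. The list of 5 blood cell genes at Rapa 10 mg/kg had 2 higher members, or 4 adjusted over the list alone (adjusted p = 0.00357 with the preset correlation), and lost its call with an estimated correlation (adjusted p = 0.0866).

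Cyp2c11, which the liver of adult male rats expresses more than that of young ones, was lower at day 28 with CsA 25, FK506 6 and Rapa 10 mg/kg, at changes from -4.26 to -4.78, and a halt of the changes that come with age was tested as a hypothesis. Of 151 genes that changed from day 1 to day 28 in rats given CsA 2.5 mg/kg, 67.5%, 72.2% and 63.6% had the opposite sign with CsA, FK506 and Rapa. Replicate 2 of CsA 2.5 mg/kg at day 28 had Alb at 13.11, and without the 4 arrays with Alb above 12 the genes numbered 99 and the shares were 68.7%, 71.7% and 68.7%. The lowest share in each case lay between the limits of 60% and 75% set beforehand, so a halt of ageing changes could be neither shown nor excluded for these genes as a set. For Cyp2c11 itself such a halt cannot be the whole cause, because from day 1 to day 28 it differed by 1.24 in vehicle rats (SE 0.81, adjusted p = 0.494) and by -0.43 in rats given CsA 2.5 mg/kg (adjusted p = 0.883).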
